A study of Homo sapiens with 3 samples.

How the data were processed

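Gene expression was measured in 3 samples of total RNA, 1 per group, on a human 3' expression array. Per the labels' protocols, cells were stably transduced, selected with antibiotics for 2 weeks, and biotin-labelled cRNA was made from 6 ug of total RNA. Samples were grouped by their titles and genotypes into empty vector, wild-type PMM1 and PMM1 R150H. The labels name the cell line in 3 ways, Cal-27, SAS and CX-1, and the descriptions of both PMM1 arrays name RAB3C, so the line is called an oral squamous carcinoma line here, as the titles and the design text have it. All 3 arrays were used.

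The deposited values are intensities on a linear scale, 1 per probe set and array. Per the submitters' processing notes they were made with MAS5, with version and settings not given in the sources used here. Exactly equal values were found on the empty-vector and wild-type arrays for 41.7% of probe sets and on all 3 arrays for 22.9%, which a signal computed array by array would seldom give, so the summary of probes into probe sets, and how far the arrays share information, is not settled. Such ties make many differences exactly 0 and narrow the spread of differences between arrays. The 2% trimmed means of the arrays were 152, 142 and 109, so the deposited arrays do not share a scaling target. No scanner files were used here, so background correction was not repeated.

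Intensities were used as deposited and turned to log2. A floor was set at each array's 50th percentile over non-control probe sets (20.6, 20.7 and 21.7), and only probe sets above the floor on both arrays entered a difference. Gene names come from the platform's annotation, which can be old. They were looked up by gene identifier in the RefSeq gene table of GRCh38.p14, which held 41043 of the 41097 probe sets naming 1 gene and changed 0 symbols. A further 1801 probe sets named several genes and 11777 none, and these name no gene here. In the fixed lists, 3 older symbols were matched to current ones. A gene's value is the mean log2 difference over its probe sets, and its error is the SD over them, which is not a replicate error. Genes with 1 probe set have no error. Ratios of genes near the floor on 1 array rest on background there and give the size of a difference only roughly. A gene at the floor on 1 array by all its probe sets is given as a bound, the brightest probe set of the other array over the floor. Genes were counted as higher or lower at 2-fold, with no test, since each group has 1 array. Array counts per group limit precision, and intervals on shares of genes are exact binomial intervals that treat genes as independent.

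The named genes were, for each comparison, PMM1, PMM2 and RAB3C, the 8 highest and 8 lowest genes with at least 2 probe sets of 1 sign, the 5 highest and 5 lowest with 1 probe set, the 3 highest and 3 lowest bounds, and up to 4 members of each list with the largest difference of at least 2-fold. Y-linked genes and XIST were left out. Genes named to follow such a gene into another comparison, and those of the windows and of the families in the closing part, were chosen after their values were seen. The 29 lists covered glycosylation, stress responses, metabolism, signalling, cell cycle, squamous and mesenchymal genes, markers of other cell types, and control groups. Each list's median was placed among 10000 random lists of the same size drawn from 10 bins of mean level, as a description of these arrays. Lists outside the central 95% (percentiles 2.5 to 97.5) are called above or below the random lists. The lists, the size rule, the rule for named genes and most alternatives were fixed before the data were examined.

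The comparison of both PMM1 arrays with the same control was set beside 100 simulations of unchanged arrays sharing that control. Windows of 50 neighbouring genes, moved by 5 genes, were summarised by a mean without the 5 highest and 5 lowest, minus the same measure over all genes, and compared with 100 shufflings of gene order. Stretches of passing windows were set against 1000 random gene sets. The steps were tested on simulated data for the wild-type comparison. Of 50 genes per size and direction among 12542 genes, planted 3-fold differences were called in 98.0% in each direction. Planted 8-fold higher differences were called in 100.0% and 8-fold lower ones in 84.0%, the rest having dropped to the floor. Of 12350 unplanted genes 0 were called. The simulated noise was normal and smaller than the observed spread of this comparison, whose SD over genes was 0.38. The 0 unplanted calls therefore give no rate of false calls for the real arrays. With 12326 genes in order, 0 windows passed with nothing planted and a planted run of 150 genes was found.

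Alternatives were quantile normalization of the 3 arrays, setting the median difference to 0, floors at the 30th and 70th percentile, log2(value + 32), the brightest probe set alone, leaving out probe sets with IDs ending in _x_at or _s_at, and a 3-fold rule. A rule that every probe set of a gene differ at least 2-fold was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.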

Results

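Total RNA from 3 cultures of a human oral squamous carcinoma line was measured on 3 short-oligonucleotide expression arrays, 1 array per culture. The cultures carried an empty lentiviral vector, a vector for wild-type PMM1, or a vector for the R150H form of PMM1, and had been kept under antibiotic selection for 2 weeks. PMM1 is phosphomannomutase 1, an enzyme that interconverts mannose phosphates on the route to the sugar donors of protein glycosylation. The array titles name the line Cal-27, while the series design names SAS and the array descriptions name CX-1 and, for both PMM1 arrays, expression of RAB3C. Groups were taken from the titles and genotypes. Because each group has 1 array, no p-value and no test between groups is given, and the number of arrays limits the precision of every value. The percentiles, shufflings and intervals below run across genes or probe sets and describe these 3 arrays only. Differences are log2 ratios of intensities, averaged over the probe sets of a gene, and the ± value is the SD over those probe sets, which covers disagreement between probe sets only.

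The 3 arrays had close medians and unequal bright ends. The median intensity over all probe sets was 20.6 on the empty-vector array, 20.7 on the wild-type array and 21.7 on the R150H array, while the 90th percentile was 534, 494 and 354. Across probe sets above the floor, Pearson's r of the log2 intensities was 0.983 between the empty-vector and wild-type arrays, 0.937 between the wild-type and R150H arrays, and 0.919 between the empty-vector and R150H arrays. These correlations are across probe sets, which are not independent replicates. Probe sets for bacterial and phage transcripts added to every hybridisation read lower on the R150H array. Of their 18 probe sets, 0 were at least 2-fold below the empty-vector array on the wild-type array and 3 were on the R150H array. A cre probe set read 10761 on the empty-vector array and 326 on the R150H array, a bioD probe set 3132 and 209, and a bioB probe set 384 and 94.9. Other probe sets of the same 3 transcripts stayed within 2-fold on these arrays. Examples are 11745 and 10651 for cre, 3698 and 3035.5 for bioD, and 330 and 291 for bioB. Over all 18, the median log2 difference from the empty-vector array was -0.22 on the wild-type array and -0.49 on the R150H array.

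**Figure D1:**
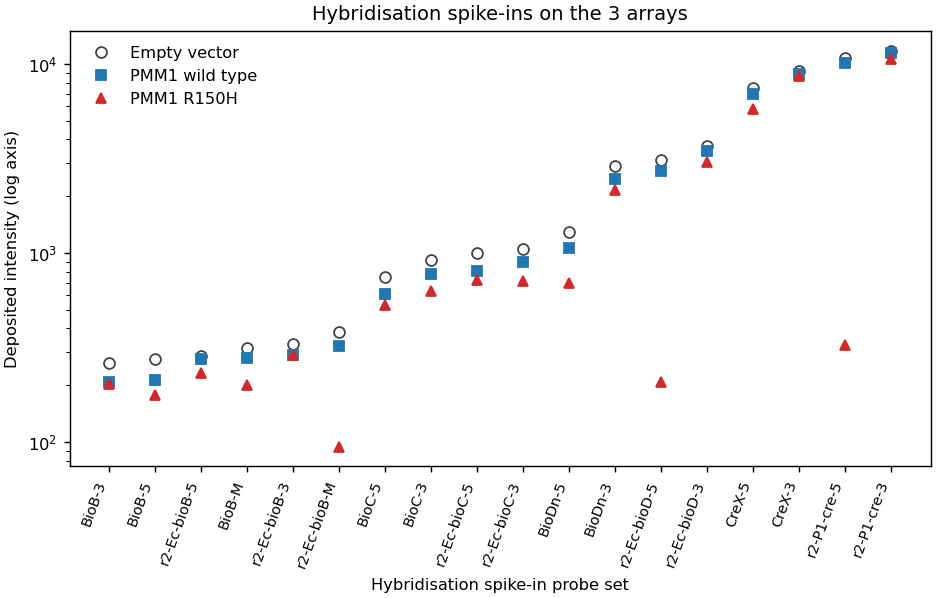
Deposited intensity (log axis) of the 18 hybridisation spike-in probe sets, ordered by their level on the empty-vector array, with 1 symbol per array. On the R150H array 3 probe sets (bioB, bioD and cre) lie far below both other arrays, and the remaining ones lie at or below the wild-type array.

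PMM1 itself was read by 1 probe set (chromosome 22), which gave 283 on the empty-vector array, 376 on the wild-type array and 322 on the R150H array. The log2 difference from the empty vector was 0.41 for wild type, a level that 729 of 12637 measured genes reached or passed, and 0.18 for R150H. The R150H array was lower than the wild-type array by a log2 difference of -0.22, but after quantile normalization this difference was 0.25 and the R150H difference from the empty vector 0.76. Whether this probe set lies within the sequence carried by the vector is not known here, so its level is a weak check of the labels. No probe set named PMM2 alone. The 4 probe sets of RAB3C, a small GTPase of secretory vesicles, lay at or below the floor on all 3 arrays, between 4.82 and 10.4.

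The first comparison asked which transcripts differed between cells with wild-type PMM1 and cells with the empty vector. Keratins of the basal layer of squamous epithelium were far higher with wild-type PMM1. KRT14 went from 86.5 on the empty-vector array to 6067, a 70.1-fold difference, KRT15 was 11.8-fold higher, and their partner KRT5 was 2.22-fold higher. The collagenases MMP13 and MMP1 read 21.9 and 26.8 on the empty-vector array, close to its floor of 20.6, and 1009 and 383 with wild-type PMM1, and interferon-induced genes such as IFI6 were higher. In the other direction, the chemokine CCL2 was 5.35-fold lower, the cyclin CCND2 9.11-fold lower and the actin-binding tropomyosin TPM1 8.21-fold lower. In all, 155 of 12637 measured genes were at least 2-fold higher and 227 were at least 2-fold lower.

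The basal keratinocyte list had a median log2 difference of 0.18 over 16 measured members, at percentile 99.99 of 10000 random lists matched for level, with 3 members at least 2-fold higher (KRT14 6.13, KRT15 3.56 and KRT5 1.15) and 0 lower. The keratinocyte differentiation list had a median of 0.23, above all random lists, with 4 of 16 members at least 2-fold higher and 1 lower. By their brightest probe set, 16 of the 29 members on the array lay above the floor with the empty vector. The differentiation genes KRT1, IVL, LORICRIN and FLG lay below it on all 3 arrays, so the median does not cover them. Its largest values were those of the squamous cell carcinoma antigen SERPINB3, at 4.31, and the kallikrein proteases KLK10, from 20.8 near the floor, and KLK5, at 2.78 and 1.41, while the antimicrobial protein gene S100A7 was at -1.32. SERPINB4, a close paralogue of SERPINB3, was at the floor on the empty-vector array and at least 12.7-fold higher with wild-type PMM1, and SERPINB13 was at 2.37 ± 1.46 over 3 probe sets. Probes for SERPINB3 and SERPINB4 can read both transcripts. Within the epithelial adhesion list, whose median of -0.08 lay at percentile 18.1, 3 of 25 members were at least 2-fold higher and 0 lower. All 3 encode desmosome proteins of squamous cells: PKP1 at 2.45, DSC3 at 1.41 ± 0.18 and DSG3 at 1.36 ± 0.09.

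Matrix-degrading enzymes and their inhibitors had a median of 0.16 over 22 members, above all random lists, but its members went both ways, 3 at least 2-fold higher and 4 lower. MMP13 was at 5.53 and MMP1 at 3.84, and the protease inhibitor SERPINE2 was 8.01-fold higher, while the lysosomal protease CTSB was at -1.70 ± 0.41 over 5 probe sets. The mesenchymal list was lower, with a median of -0.22 at percentile 0.02, and 4 of 22 members at least 2-fold lower and 2 higher. Fibronectin FN1 was at -1.48 ± 0.74, S100A4 at -1.49, SPARC at -1.39 ± 1.24 and the growth factor TGFB2 at -1.33 ± 0.75. VIM was among the 2 higher members, at 1.22 (28.6 on the empty-vector array, near the floor, and 66.7 with wild-type PMM1). The brightest probe set of SNAI2 read 572 and 1172 on these arrays.

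Of 26 measured type I interferon response genes, 9 were at least 2-fold higher and 0 lower, and the median of 0.66 lay above all random lists. IFI6 was 4.01-fold higher, and in log2 the transcription factor subunit IRF9 was at 1.72, and IFI27 and IFIT1 at 1.65 each. The list of NF-kB targets and inflammatory cytokines lay below all random lists, with a median of -0.31. Of its 25 members 5 were at least 2-fold lower, among them CCL2 at -2.42, the siderophore-binding LCN2 at -2.37, CCL20 at -1.97 and the calprotectin subunit S100A9 at -1.47, and 2 were at least 2-fold higher. Immediate early genes had a median of 0.14 at percentile 99.98, with EGR1 at 2.85 ± 0.26 and the ERK phosphatase DUSP6 at 2.48 ± 0.30 as the 2 members of 20 that were at least 2-fold higher. The hypoxia list had a median of -0.29 at percentile 0.01, with only BNIP3L, a mitophagy receptor, past the size rule at -1.41 ± 0.21. The stemness-associated list had a median of 0.27 at percentile 99.99, with 1 of 11 members at least 2-fold higher, the efflux transporter ABCG2 at 1.30.

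**Figure D2:**
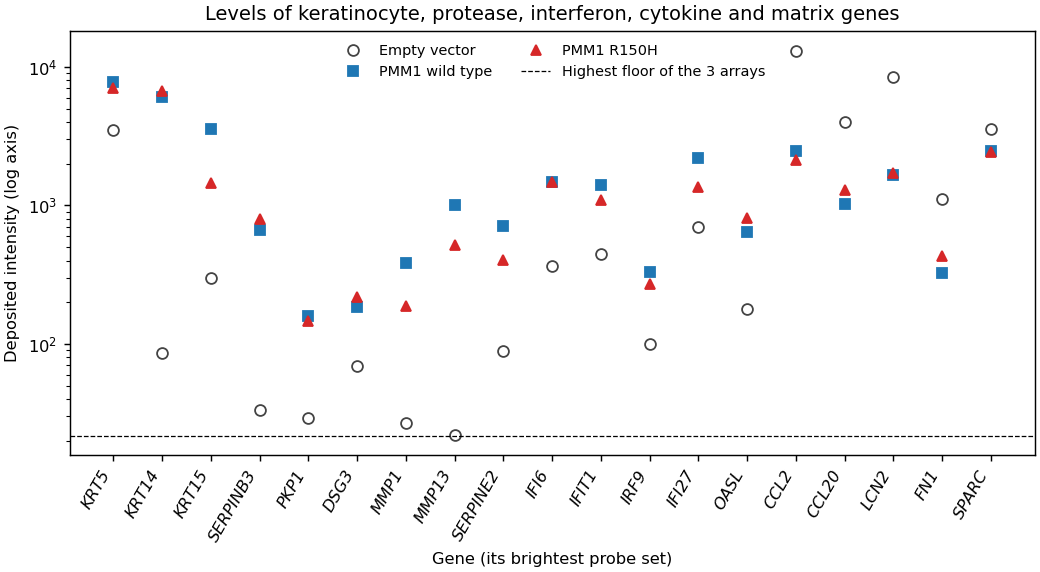
Deposited intensity (log axis) of the brightest probe set of 19 keratinocyte, protease, interferon, cytokine and matrix genes on the 3 arrays, with the highest of the 3 floors as a dashed line. KRT14 was at 86.5 on the empty-vector array and at 6067 and 6753 on the PMM1 arrays, and CCL2 at 13159 on the empty-vector array and at 2461 and 2122 on the PMM1 arrays.

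Lists for the pathway PMM1 belongs to lay at different places among the random lists. None of 27 mannose and nucleotide sugar genes reached 2-fold (0 higher, 0 lower), and their median was 0.00 at percentile 83.9. The lipid-linked oligosaccharide and oligosaccharyltransferase list had a median of 0.01 at percentile 97.8, with 1 of 26 members at least 2-fold lower, the catalytic subunit STT3B at -1.03. The GPI anchor list had a median of 0.07 at percentile 99.9, and 0 of 24 members reached 2-fold. Among N-glycan trimming and branching genes, 5 of 24 were at least 2-fold lower and 0 higher, where 1.80% of all measured genes were as low, with a median of -0.10 at percentile 6.12. They included the branching enzymes MGAT4A at -2.40, MGAT5 at -1.20 and MGAT4B at -1.09 ± 0.25, and the cytosolic deglycosylase NGLY1 at -1.22. The unfolded protein response list had a median of -0.14 at percentile 3.82 and 0 of 23 members past 2-fold.

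Other single genes stood out by size. With 2 or more probe sets, CAMK2N1 was at 2.06 ± 0.17, the mitochondrially encoded ND4 at 1.83 ± 0.54, the aldo-keto reductase AKR1C2 at 1.68 ± 0.01 and the heparin-binding cytokine PTN at 1.65 ± 0.14. Lower were CCND2 at -3.19 ± 0.45, TPM1 at -3.04 ± 0.10, the sialyltransferase ST6GALNAC5 at -2.98 ± 0.17, the pantetheinase VNN1 at -2.68 ± 0.68, the palmitoyltransferase ZDHHC2 at -2.27 ± 0.15, PDZK1IP1 at -2.11 ± 0.21 and the endothelin precursor EDN1 at -2.04 ± 0.80. MYADM was at -2.54 ± 1.86 and LOC389834 at 1.73 ± 0.78, both with a wide spread. With 1 probe set, TUSC1 was at -3.60, the glycoprotein hormone STC1 at -3.03, COXFA4L3 at -2.97, ALOX5AP, the activating protein of leukotriene synthesis, at -2.90, and the sialomucin PODXL at -2.65. BEX2 and the protein kinase A subunit PRKAR2B were at the floor with the empty vector and at least 14.2-fold and 9.16-fold higher with wild-type PMM1. The coagulation inhibitor TFPI, the interleukin subunit EBI3 and the branching enzyme GCNT2 were at the floor with wild-type PMM1 and at least 7.97-fold, 4.52-fold and 3.59-fold lower.

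The p53 list lay above the central 95% of random lists, with a median of 0.07 at percentile 99.7 and 1 of 21 members at least 2-fold lower, the stress cytokine GDF15 at -1.34. Markers of colorectal epithelium lay below it, with a median of -0.15 over 7 members, 0 of them past 2-fold. In all, 9 of the 29 lists lay above the central 95%, 4 below and 16 within. Those within included the integrated stress response (median -0.04, percentile 36.7, NUPR1 at -1.53 and ALDH1L2 at -1.35), NRF2 targets (-0.04, percentile 38.2, AKR1C2 and AKR1C1 3.20-fold and 2.83-fold higher), integrins (0.00, percentile 72.1, ITGA4 higher at 1.38), fibroblast markers (0.00, percentile 55.3, VIM higher at 1.22) and leukocyte markers (-0.01, percentile 42.4, the class II gene HLA-DRA lower at -1.47 ± 0.02). Glycolysis had a median of -0.02 at percentile 70.3, oxidative phosphorylation -0.06 at percentile 39.9, cholesterol synthesis 0.00 at percentile 85.8, G1/S genes -0.03 at percentile 62.3, G2/M genes -0.03 at percentile 63.2, ribosomal proteins -0.02 at percentile 77.1 and housekeeping genes -0.08 at percentile 33.5, and 0 members of these lists reached 2-fold.

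For genes called by their brightest probe set, a further probe set had the same direction in 97.3% of those higher (exact 95% binomial interval 90.6 to 99.7) and in 98.7% of those lower (95.5 to 99.8), against 82.8% over all genes, leaving out differences of 0. With a floor at the 70th percentile the protease list turned to a median of -0.12 relative to all genes, and the keratinocyte differentiation, colorectal and oligosaccharide lists no longer stood outside the random lists, nor did the p53 list when the brightest probe set alone was used.

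The second comparison set the R150H array against the empty-vector array. The genes highest with wild-type PMM1 were high here as well. KRT14 was 78.1-fold higher (86.5 against 6753), SERPINB3 was 23.6-fold higher, MMP13 read 515 against 21.9 near the floor, and 8 of 26 interferon genes were at least 2-fold higher with 0 lower. A much larger group was lower. Of 12560 measured genes 1601 were at least 2-fold lower and 112 were at least 2-fold higher, so that 6.54% of the genes past the rule were higher. After quantile normalization of the 3 arrays the counts were 940 lower and 289 higher, with 23.5% higher, and the median of all genes moved from -0.11 to 0.13. List medians are therefore given beside the median of the matched random lists or with their place among those lists.

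The keratinocyte and interferon lists again lay above the random lists. The keratinocyte differentiation list had a median of 0.28 against -0.07 for random lists and lay above all of them, with 4 of 16 members at least 2-fold higher and 2 lower. SERPINB3 was at 4.56, KLK10 at 3.11 and the elastase inhibitor PI3 at 2.36, while the cystatin CSTA was at -3.03. SPRR1B, a cornified envelope precursor, was at the floor on the empty-vector array and at least 12.5-fold higher. The basal keratinocyte list had a median of 0.04 against -0.19, at percentile 99.95, with KRT14 at 6.29 and KRT15 at 2.27 higher and the laminin chain LAMB3 lower at -1.32. The serine protease TMPRSS4 was at 3.06. Interferon genes had a median of 0.59 against -0.27, above all random lists, with IFI6 at 2.02, OASL at 1.85 ± 0.46, the antiviral RSAD2 at 1.68 ± 0.61 and IRF9 at 1.42. Desmosome genes PKP1, DSC3 and DSG3 were at 2.33, 1.51 ± 0.31 and 1.48 ± 0.26, within an epithelial adhesion list whose median was -0.28 at percentile 43.0 and in which the splicing factor ESRP1 was at -2.38 ± 3.07.

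The cytokine and hypoxia lists lay below the random lists by their medians, with most members short of 2-fold. The NF-kB and cytokine list had a median of -0.68 against -0.21, at percentile 0.08, with 10 of 25 members at least 2-fold lower and 1 higher. S100A9 was at -4.64, CCL2 at -2.63, the NF-kB inhibitor NFKBIA at -2.38 and IL1A at -2.34. The hypoxia list had a median of -0.66 against -0.22, at percentile 0.71, with 7 of 20 lower, among them NDRG1 at -2.31 and BNIP3L at -1.66 ± 0.29. Proteases and their regulators had a median of -0.52 against -0.21, at percentile 2.11, with MMP13 at 4.56 and MMP1 at 2.81 among 3 that were higher and the cathepsins CTSL at -2.46 and CTSB at -2.31 ± 1.13 among 8 that were lower. The stemness-associated list had a median of 0.27, above all random lists, although MYC and ALDH1A3 were at -4.40 and -1.57 and 0 members were at least 2-fold higher. Fibroblast markers had a median of 0.28 at percentile 98.6, with VIM at 1.19 the 1 member of 6 past 2-fold.

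In this comparison 12.7% of all measured genes were at least 2-fold lower and 0.89% at least 2-fold higher. Among glycosylation lists, 5 of 27 mannose and nucleotide sugar genes were at least 2-fold lower and 0 higher. Their median was -0.19 against -0.26 for random lists, at percentile 73.3. The sialic acid synthase NANS was at -3.81, the phosphomannose isomerase MPI at -1.41 ± 1.80, GMPPA at -1.40 and UAP1 at -1.35. In the oligosaccharyltransferase list, at percentile 86.2, OST4 was at -4.45, DPAGT1 at -1.82 and DDOST at -1.54 ± 0.75. In the N-glycan list, at percentile 31.6, MGAT4A was at -2.09 ± 1.22 and the core fucosyltransferase FUT8 at -1.91 ± 1.93. The GPI anchor list had a median of 0.00 at percentile 99.5, with 5 of 24 members lower, such as PIGS, 7.99-fold lower, and PIGC at -1.49 ± 0.10. Of 23 unfolded protein response genes, 4 were lower, among them the disulfide isomerases PDIA3 at -2.61 ± 3.10 and PDIA4 at -1.90 ± 0.54, with a median of -0.55 at percentile 2.88.

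Of the genes with the lowest values, many were read by 1 or 2 probe sets. With 1 probe set, the chromatin protein gene DEK was at -6.89 (4621 against 38.8), the electron transfer flavoprotein ETFA at -6.44, the vesicle protein VAMP8 at -5.98, superoxide dismutase SOD1 at -5.74 and the histone mRNA binding SLBP at -5.74. With 2 probe sets, the cyclophilin PPIB was at -4.11 ± 1.19 and the sorting nexin SNX6 at -3.96 ± 0.85. For others the probe sets of a gene lay far apart. CNBP was at -6.93 by 1 probe set and at -1.01 by the other, TOMM20, a mitochondrial import receptor, at -6.70 and -1.01, and the signal peptidase subunit SEC11A at -6.35 and -0.80, and JPT1, RCAN1 and MKRN1 had SDs of 2.79, 2.47 and 2.69. MITD1, LAP3 and NDUFAF3 were at the floor on the R150H array and at least 40.8-fold, 39.0-fold and 33.0-fold lower. Cell cycle genes with values past 2-fold were all lower, as were most genes past 2-fold in this comparison. Among them were GINS1 at -4.82, RRM2 at -3.87, CDC25B at -4.16 and AURKB at -4.12. The G1/S and G2/M lists lay within the random lists, at percentiles 14.8 and 36.1. The transcription factors ATF4 and CEBPB were at -2.80 and -2.84, in an integrated stress response list at percentile 49.6.

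Among genes whose brightest probe set was at least 2-fold lower, the next probe set was also at least 2-fold lower in 25.0% (exact 95% interval 22.0 to 28.1). Over all genes, the next probe set was at least 2-fold different in the direction of the brightest, higher or lower, in 11.9%. It had the same direction at any size in 80.8% of the lower genes (77.6 to 83.6), against 3081 of 4002 over all genes. Counting only genes with 2 or more probe sets, all of them at least 2-fold lower, a rule added after the data were seen, left 132 of 5947 genes lower and 11 higher. In 100 shufflings of probe sets the count of lower genes had a mean of 69.7 and a maximum of 91. The 132 do not leave out genes that were also low with wild-type PMM1. The keratinocyte differentiation list turned to -0.84 relative to all genes with a floor at the 70th percentile, and the immediate early, basal keratinocyte, stemness, fibroblast, protease, hypoxia and GPI anchor lists lost their place outside the random lists under at least 1 alternative.

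The third comparison set R150H against wild-type PMM1, the contrast of the mutant with its parent form. Few genes were higher with R150H. The serine protease TMPRSS4 was 4.09-fold higher (55.9 against 229), and the squamous genes SPRR1B and PI3 were higher at 1.37 and 1.24, while KRT14 differed by 0.15 and IFI6 by 0.01. Of 12583 measured genes 20 were at least 2-fold higher and 1197 at least 2-fold lower. After quantile normalization 35 were higher and 819 lower, and the median of all genes moved from -0.07 to 0.15.

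The interferon list held 0 of 27 members past 2-fold, with a median of -0.06 against -0.15 for random lists, at percentile 95.8. Such counts average the probe sets of a gene and can hide a low one. On the empty-vector, wild-type and R150H arrays the brightest probe set of RIGI read 491, 688 and 116, and that of SAMD9 323, 666 and 284. Other higher genes were dim. XNDC1N at 1.72, the guidance molecule NTNG1 at 1.72, the neuronal transcription factor NEUROD2 at 1.70 and RGS11 at 1.43 each had 1 probe set that read below 100 on both arrays. With 2 or more probe sets, TAL1 was at 0.82 ± 0.76, RSAD2 at 0.82 ± 0.32, VSNL1 at 0.65 ± 0.18, the aquaporin AQP3 at 0.61 ± 0.18 and IGFBP5 at 0.60 ± 0.24, and CAPN5, CCDC13 and HMCN2 lay between 0.55 and 0.59. GUCY1A2, DNALI1 and GALR2 were at the floor with wild-type PMM1 and at least 9.54-fold, 7.28-fold and 6.73-fold higher with R150H.

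Of the 29 lists, 2 lay below the random lists, those of proteases and of G1/S genes. The protease list had a median of -0.47 against -0.11, at percentile 0.14, with 7 of 23 members at least 2-fold lower and 0 higher. CTSL was at -2.89, the metalloprotease inhibitor TIMP1 at -2.39, CTSV at -2.12 and matrilysin MMP7 at -1.59. The G1/S and DNA replication list had a median of -0.39 against -0.17, at percentile 1.55, with 7 of 27 lower, such as SLBP at -5.63, GINS1 at -4.82, RRM2 at -3.96 and UNG at -2.89. Immediate early genes lay within the random lists, at percentile 31.7, with 4 of 21 members lower and 0 higher, among them MYC at -4.58 and EGR1 at -1.42 ± 1.08. KRT15 was at -1.29 and SERPINB4 at -2.46. Keratinocyte differentiation stood above the random lists at percentile 99.96 with a median of 0.05 and members on both sides, 2 of 19 higher and 3 lower. The epithelial adhesion and integrated stress response lists stood above them by their medians of 0.00 and -0.02, at percentiles 99.95 and 99.55, although their largest differences were lower. In the integrated stress response list 5 of 23 members were at least 2-fold lower and 1 higher, with CEBPB at -2.80, ATF4 at -2.46, PHGDH at -2.05 and SHMT2 at -2.04 ± 1.89 lower and NUPR1 at 1.16 higher, and in epithelial adhesion 1 of 25 was lower and 0 higher, ESRP1 at -2.08 ± 2.94. Of 27 mannose and nucleotide sugar genes 5 were lower and 0 higher, at percentile 39.9, led by NANS at -3.90. In the oligosaccharyltransferase list OST4 was at -4.62. Between the PMM1 arrays 9.51% of all measured genes were at least 2-fold lower.

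Of the 5 lowest genes with 1 probe set, DEK at -6.71, ETFA at -6.18, VAMP8 at -5.70 and SLBP at -5.63 were also among the 5 lowest of the second comparison, and the proteasome subunit PSMC3 at -5.63 was not. The helicase DHX15 was at -3.42 ± 0.15, PPIB at -3.90 ± 1.17, SNX6 at -3.56 ± 1.26 and DNAJC9 at -3.61 ± 1.92, while JPT1, CNBP, TOMM20 and MKRN1 again had probe sets far apart, with SDs of 2.84, 4.39, 4.04 and 2.57. LAP3, MITD1 and LYSET were at the floor with R150H and at least 43.4-fold, 35.1-fold and 23.4-fold lower. Among genes lower at least 2-fold by the brightest probe set, the next was also at least 2-fold lower in 15.8% (exact 95% interval 13.0 to 19.0). Over all genes, the next probe set was at least 2-fold different in the direction of the brightest, higher or lower, in 7.94%. It had the same direction at any size in 77.1% of the lower genes, against 75.0% over all genes. Of 5995 genes with 2 or more probe sets, 51 had all of them at least 2-fold lower, with 0 higher. The G1/S list no longer stood below the random lists under quantile normalization, nor did the integrated stress response list above them with the brightest probe set alone.

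**Figure D3:**
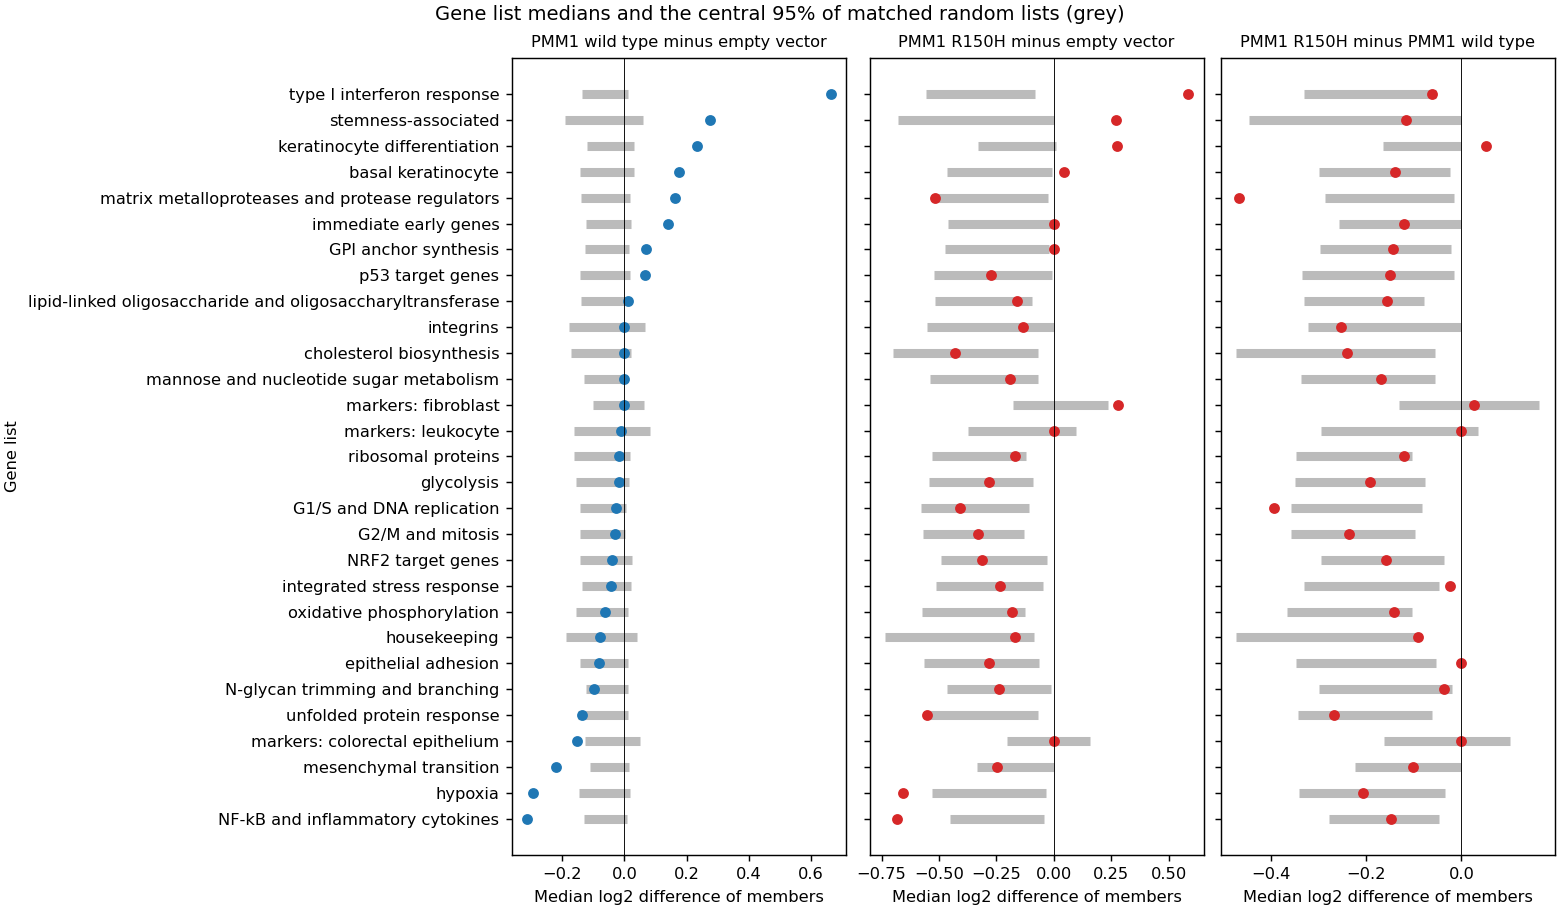
Median log2 difference of each of the 29 gene lists (points) in the 3 comparisons, with the central 95% of 10000 random lists matched for level (grey bars). The scales of the panels differ. Type I interferon genes lie above the bar at 0.66 and 0.59 in the comparisons with the empty vector and within it at -0.06 between the PMM1 arrays.

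Both PMM1 arrays differed from the empty-vector array in many of the same genes. KRT14, SERPINB3, MMP13, MMP1 and KRT15 were high on both, and CCND2, TPM1, TUSC1 and CCL2 low on both. Across 12464 genes measured on all 3 arrays, 78 were at least 2-fold higher and 206 at least 2-fold lower in both comparisons, and 1 went in opposite directions. Independent lists of the same sizes would share 1.37 and 28.7 genes. The differences correlated across genes with r = 0.507 (Spearman's rho 0.608), but both contain the same empty-vector array. In 100 simulations of unchanged arrays sharing 1 control, r was 0.502 with noise as between the wild-type and empty-vector arrays and 0.501 with noise as between the PMM1 arrays. The simulated r was nearly the same at both noise sizes, as equal noise on all arrays gives whatever its size. The real arrays were unequal, with an SD over genes of 0.38 for wild type minus empty vector and 0.75 for R150H minus empty vector. The closeness of the observed r to the simulated r therefore decides nothing about a shared effect or the shared control. The noise was set from observed differences, so any real difference between those arrays counts as noise in the simulations. The observed covariance of 0.145 lay between the simulated values of 0.0743 and 0.251, and the simulated overlaps were 62.3 higher (maximum 83) and 62.0 lower (maximum 81) with the smaller noise and 312 and 309 with the larger. With 1 control array the control cannot be split. As deposited, the 78 shared higher genes lie within the range with the smaller noise, so all of that overlap may come from the shared control. The 206 shared lower genes lie above the range with the smaller noise and below the mean with the larger. After quantile normalization 130 were shared higher and 106 shared lower, above the smaller-noise maxima of 73 and 78 and below the larger-noise means of 216 and 211. With a floor at the 30th percentile 96 were shared higher (smaller-noise maximum 86), and at the 70th percentile 34 (maximum 56). The place of the shared higher genes thus depends on the processing.

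**Figure D4:**
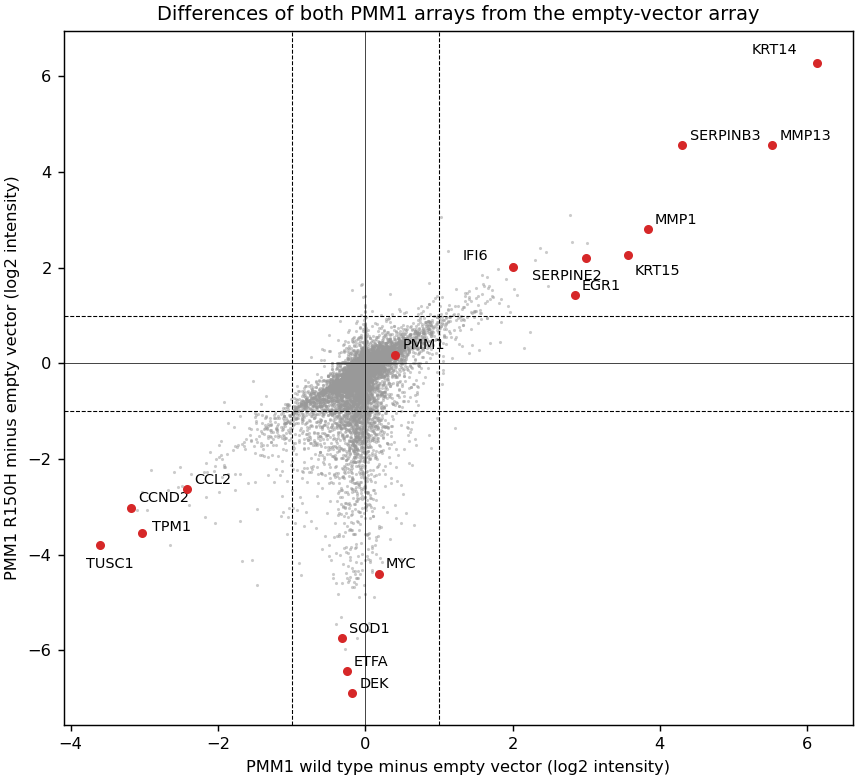
Log2 difference from the empty-vector array for wild-type PMM1 (horizontal) and R150H (vertical), 1 point per gene, with dashed lines at 2-fold and named genes in red. KRT14, at 6.13 and 6.29, and CCND2, at -3.19 and -3.01, lie near the diagonal, and DEK, at -0.18 and -6.89, is low on the R150H array alone.

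Neighbouring genes shifted together on parts of 6 chromosomes, a measure added after the data were seen. Gene order was taken from the GRCh38.p14 annotation, and no coordinates are given because the array table names no build. In windows of 50 neighbouring measured genes, 146 of 2306 windows passed the 95th percentile of the most extreme window of 100 shuffled gene orders in the wild-type comparison, 67 of 2290 in the R150H comparison and 0 of 2294 between the PMM1 arrays. Each comparison had its own threshold, at a deviation of 0.159, 0.388 and 0.338, so the counts are not on 1 scale, and between the PMM1 arrays the lowest window was at -0.33. Relative to all genes, the stretch from TRNT1 to CRYBG3 on chromosome 3 (335 genes) was at -0.43 with wild-type PMM1 and -0.40 with R150H, and that from RPL23AP53 to GGH on chromosome 8 (185 genes) at -0.44 and -0.47. PLEKHG4B to FYB1 on chromosome 5 was at -0.19 on both. There only 57.5% of genes lay below the centre of all genes with wild-type PMM1, and 55.0% with R150H. With wild-type PMM1 this share was 79.7% in the chromosome 3 stretch and 78.4% in that of chromosome 8. Higher were BATF to CRIP1 on chromosome 14 (140 genes), at 0.34 and 0.30, ASXL1 to LIME1 on chromosome 20 (230 genes), at 0.21 and 0.18, and H1-2 to PPP1R11 on chromosome 6 (50 genes), at 0.17 and 0.22. In the chromosome 6 stretch 15 of the genes are histone genes. A stretch found in the R150H comparison, SSR1 to H3C3 on chromosome 6 (55 genes), was at -0.38 with R150H, at -0.08 with wild-type PMM1 and at -0.19 between the PMM1 arrays, where 44.4% of its genes lay below the centre of all genes. Only genes picked by the rule for named genes in the wild-type comparison were looked up in these stretches. Of those, STT3B and NGLY1 lie in the chromosome 3 stretch, ZDHHC2, STC1, BNIP3L and CTSB in that of chromosome 8 and IFI27 in that of chromosome 14.

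**Figure D5:**
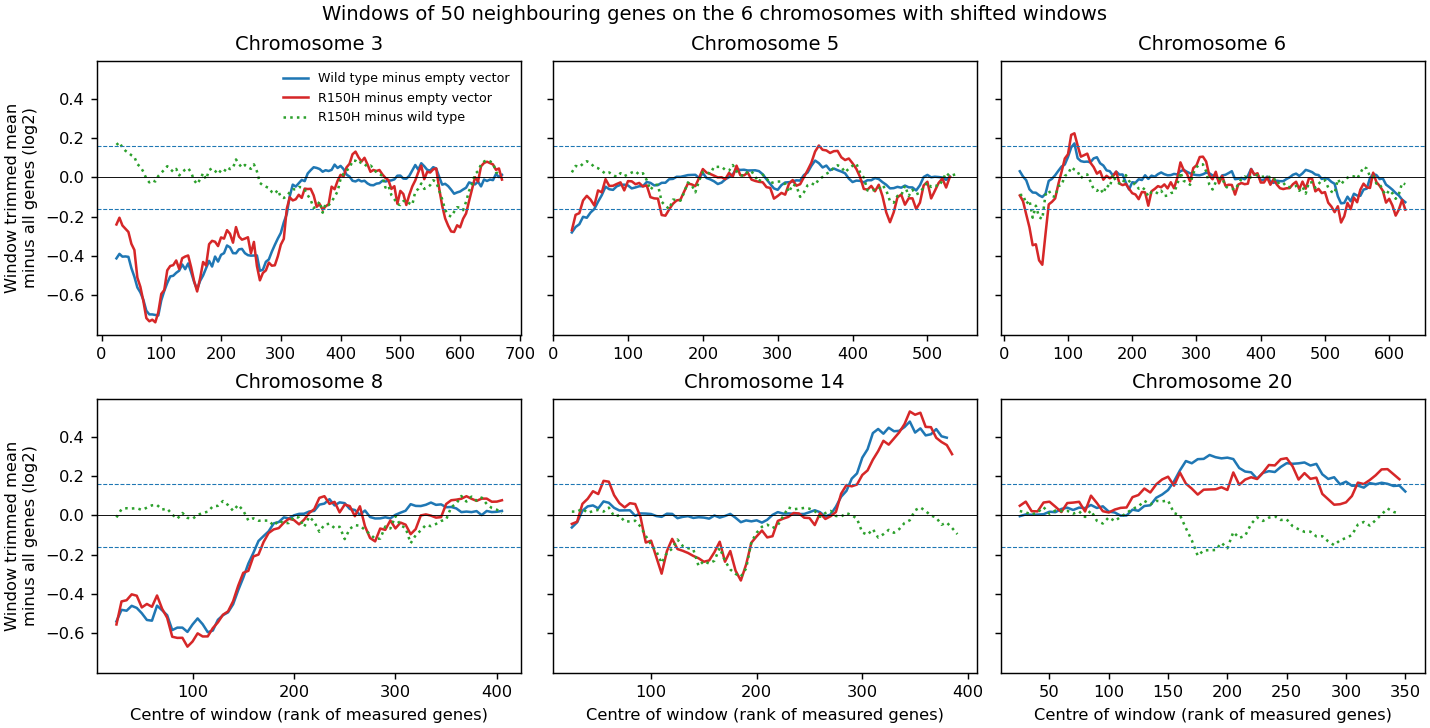
Trimmed mean log2 difference of windows of 50 neighbouring genes, relative to all genes, along the 6 chromosomes with shifted windows, for the 3 comparisons. The horizontal axis is the rank of measured genes along the chromosome, and dashed lines at 0.159 and -0.159 mark the threshold of the wild-type comparison only.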

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

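The rule that every probe set of a gene differ at least 2-fold was chosen only after the result was seen, and the other alternatives here were planned. List values here are medians relative to all genes, while weaker and stronger refer to a list's place among the random lists: a weaker list came to lie within their central 95% and a stronger one outside it, whatever the size of its median. Over the alternatives, list results stayed the same in 392 cases, were weaker in 29, stronger in 12 and reversed in 2, and values of the named genes stayed within the SD over their probe sets (the median SD of the comparison for genes with 1 probe set) in 1471 cases, moved beyond it in 287 and reversed in 5. Of the counts of genes, 30 stayed within 1.5 times and 24 moved. No paired analysis was possible because each group has 1 array. Intensities near background limit what can be seen for dim genes, which the floors test. The cause was not tested for any of these shifts.

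With quantile normalization, R150H minus empty vector had 289 genes higher and 940 lower, and R150H minus wild type 35 higher. PMM1 was at 0.76 and 0.25 in these, and the correlation of the 2 differences from the empty vector was 0.486. Wild type minus empty vector had the oligosaccharide list at 0.0871 (weaker) and N-glycan genes at -0.0589 (stronger). R150H minus empty vector had weaker immediate early (0.15), basal keratinocyte (0.18), protease (-0.10) and fibroblast (0.11) lists, and R150H minus wild type a weaker G1/S list (-0.14).

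With a floor at the 30th percentile, 192 genes were higher in R150H minus empty vector and 88 in R150H minus wild type. Weaker lists were oligosaccharide (0.00, wild type minus empty vector), immediate early (0.0158), protease (-0.40) and fibroblast (0.0880, all 3 in R150H minus empty vector), and G1/S (-0.29, R150H minus wild type), while housekeeping genes were stronger at -0.0483. With a floor at the 70th percentile, 88 genes were higher in wild type minus empty vector, 36 in R150H minus empty vector and 2 in R150H minus wild type, where HLA-DRA turned to 0.24. In wild type minus empty vector, oligosaccharide genes (0.0307), keratinocyte differentiation (0.10) and colorectal markers (-0.47) were weaker, N-glycan genes (-0.15) and leukocyte markers (-0.51) stronger, and proteases reversed at -0.12. In R150H minus empty vector, immediate early (0.0922), basal keratinocyte (0.11), stemness (0.21) and fibroblast (0.28) lists were weaker and keratinocyte differentiation reversed at -0.84. In R150H minus wild type, the integrated stress response (0.0655) and G1/S (-0.13) were weaker, and interferon genes (0.11), leukocyte markers (0.25) and housekeeping genes (0.0358) stronger.

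With the brightest probe set alone, in wild type minus empty vector the oligosaccharide and p53 lists were weaker at 0.00 each, and N-glycan genes (-0.21) and the unfolded protein response (-0.18) stronger. In R150H minus empty vector, GPI anchor (0.0824), hypoxia (-0.36), immediate early (0.0487), basal keratinocyte (-0.0251), stemness (0.0824) and fibroblast (0.16) lists were weaker, and SQLE turned to 0.16. In R150H minus wild type, the integrated stress response was weaker (0.0257), interferon genes (0.0488), leukocyte markers (0.17) and housekeeping genes (-0.0205) stronger, and HLA-DRA was at 0.24, as it was without probe sets ending in _x_at or _s_at, where COX5A turned to 0.39 in R150H minus empty vector.

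With log2(value + 32), wild type minus empty vector had 76 genes higher and 146 lower, R150H minus empty vector 46 higher and R150H minus wild type 4 higher. With a 3-fold rule these were 43 and 61, then 27 higher and 772 lower, then 4 higher and 596 lower. With every probe set of a gene past 2-fold they were 17 and 46, then 11 and 132, then 0 and 51.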

Other observations

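The tests of spike-ins, of the overall distribution, of genes with every probe set below both other arrays and of segments between the PMM1 arrays were chosen only after the result was seen, and so were the shufflings of second probe sets and of gene order with a shared control, the tally of rRNA probe sets and the gene families below. The remaining tests were written before their outcome was computed. In the families and rRNA probe sets below, higher and lower count signs of any size unless 2-fold is named, and none of these groups was set against random lists. Transcripts of the mitochondrial genome, which encodes subunits of the respiratory chain, were higher with wild-type PMM1 than with the empty vector in all 7 measured genes, 5 of them at least 2-fold, with a median log2 difference of 1.31. ND6 was at 1.85, ND4 at 1.83 ± 0.54 over 2 probe sets, ND2 at 1.45, COX2 at 1.31 ± 0.13 and COX3 at 1.28. With R150H, 6 of the 7 were higher than with the empty vector and 0 reached 2-fold, with a median of 0.38 and COX1 at -0.49. After quantile normalization 7 of 7 were higher, COX1 among them, 1 reached 2-fold and the median was 0.69. In both scalings all 7 were lower than with wild-type PMM1, with a median of -0.98, or -0.73 after quantile normalization. The list of nuclear oxidative phosphorylation genes had a median of -0.06 with wild-type PMM1.

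A family of HLA class II genes, CD74 and CIITA, which serve antigen presentation, was lower with wild-type PMM1 in all 12 measured members. Of these, 4 were at least 2-fold lower, and the median was -0.49. Some differences were small and near the floor, such as CIITA at -0.24 (24.8 against 29.3) and HLA-DRB4 at -0.09 (34.4 against 36.7). HLA-DRB1 was at -1.78, HLA-DRA at -1.47 ± 0.02, HLA-DQB1 at -1.18 ± 0.92 over 6 probe sets and HLA-DPB1 at -1.07, although probes for DRB genes can read several of them. With R150H, 11 of the 12 were lower and 5 at least 2-fold, with a median of -0.40, and after quantile normalization 8 were lower and 4 higher. Of 21 histone genes, 14 were higher with wild-type PMM1, 0 lower and 7 at exactly 0, led by H2BC21 at 1.66, H2BC12L at 1.21, H2BC12 at 1.13 and H1-2 at 1.03. With R150H, 15 were higher, 3 lower and 3 at 0, with a median of 0.18, 3 at least 2-fold higher (H2BC21 at 1.57, H2BC12L and H1-2 at 1.03) and H3C8 at least 2-fold lower at -1.03, and after quantile normalization the median was 0.65 with 8 at least 2-fold higher. Of the 21 genes 15 lie in the chromosome 6 stretch from H1-2 to PPP1R11, so the family and that stretch overlap, while of the 6 outside it 5 were higher with wild-type PMM1, H2BC21 and H2BC12L at least 2-fold. Of 6 rRNA probe sets 4 were higher with wild-type PMM1 and 0 lower, and 3 were higher with R150H and 2 lower. The 5' probe sets of 2 rRNA transcripts read 696, 1514 and 2213, and 798, 1360 and 1559, on the empty-vector, wild-type and R150H arrays. Whether RNA composition or priming lies behind the histone and mitochondrial values was not tested. The keratins KRT8 and KRT18 of simple epithelium read 2523 and 9544 on the empty-vector array, while of 19 colorectal markers, these 2 included, 8 were above the floor on the empty-vector array and 7 on each PMM1 array, the next brightest being CDX1 at 53.6, 48.2 and 63.9, and KRT20 and CDH17 were below it on all 3, and 16 of 16 basal keratinocyte genes were above it on each array.

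A large set of bright probe sets was lower on the R150H array only. Of the 18 spike-ins, which do not come from the cells, 3 were at least 2-fold lower there and 0 on the wild-type array. Other probe sets of the same 3 transcripts stayed within 2-fold. The low spike-in values thus belong to single probe sets and not to the amount added. A failed measurement of part of the probe sets on that array may therefore explain a part. A difference in the overall distribution of values could account for a part, since quantile normalization brought the genes at least 2-fold lower from 1601 to 940 and those higher from 112 to 289, but not for all of it, as 172 were lower with wild-type PMM1 under that normalization. An mRNA change in the R150H cells stays open, as 48 genes had every probe set at least 2-fold below both other arrays, against a mean of 34.9 and a maximum of 52 in 100 shufflings of probe sets of like level. Which genes belong to which part is not known, and a second hybridisation of the same RNA and quantitative PCR of DEK, SOD1 and MYC would separate them.

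Many genes differed from the empty-vector array alike on both PMM1 arrays. Measurement noise of single probe sets on the empty-vector array is argued against, since among 185 genes chosen by their brightest probe set alone the second probe set had its direction in 98.9% (exact 95% interval 96.1 to 99.9, leaving out 17 genes at 0), against 81.9% over the other genes and a maximum of 69.0% in 100 shufflings of second probe sets of like level. Noise that all probe sets of a gene share, as from labelling, is not covered by this test. A deviation of the empty-vector culture or clone unrelated to PMM1 cannot be told apart from an effect common to both PMM1 forms, because there is 1 empty-vector array. As a hypothesis, the common difference in KRT14, MMP13 and interferon genes could come from either, and independent empty-vector cultures made in parallel would test it.

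Neighbouring genes shifted together more than in shuffled gene orders. A difference in chromosome copy number between the cultures is a candidate explanation for part of the wild-type differences, since 146 windows of 50 neighbouring genes passed the 95th percentile of shuffled orders, though a regional change of chromatin would give the same. In 6 of 6 segments found with wild-type PMM1 the R150H array was shifted the same way, but both differences share 1 empty-vector array. In 96 of 100 shuffled gene orders the most shifted window was shifted the same way too, so this count by itself decides nothing. A difference of the wild-type PMM1 culture alone is argued against by R150H minus wild type, which leaves out the empty-vector array. That difference lay outside random gene sets in the opposite direction in 0 of the 6 segments, with values from -0.06 to 0.04. In these segments the empty-vector array therefore stood apart from both PMM1 arrays. With 1 empty-vector array, a difference of the empty-vector culture cannot be told apart from an effect common to both PMM1 forms. Copy number profiling of DNA from the 3 cultures would test the copy number hypothesis.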
